A study of Homo sapiens with 6 samples.

How the data were processed

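Binding of the transcription factors GATA3 and RUNX1 was profiled by CUT&RUN in Jurkat cells, an established human T cell acute lymphoblastic leukaemia (T-ALL) line, here carrying TAL1 fused to an FKBP12 tag. In CUT&RUN an antibody brings a protein A/G-micrococcal nuclease fusion to chromatin, and the short DNA fragments cut out around the bound factor are sequenced. Cells were treated with DMSO or with dTAG, a class of compound that links an FKBP12-tagged protein to a ubiquitin ligase and so leads to its degradation. The labels give neither the dose nor the time of treatment. Of the 6 samples, 4 had a peak list (GATA3 and RUNX1 in DMSO and in dTAG), and the 2 IgG control samples had no list and were not analysed here. There was 1 sample per group, so no value has a replicate error and no test between treatments was possible.

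The deposited files hold 4 columns per peak, namely chromosome, start, end and a name, and give positions in bp with no height, fold enrichment, q-value, score or summit. Per the file headers, peaks were called at a q-value threshold of 0.01 with an IgG control. The submitters' processing notes name MACS2, SEACR and the genome build hg19, and the peak names have the form that MACS2 writes. Versions, the aligner, filters and which IgG library served as control are not given in the sources used here. Each list came from 1 sample and was not pooled. The highest peak end on chromosome 1 was 249240598, and coordinates are given 1-based in hg19.

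Peaks on chromosomes 1 to 22, X and Y were used, and no repeated or artefact-prone regions were filtered out here. No interval was listed more than once. Peaks of 2 lists were called overlapping when they shared at least 1 bp, and a peak that overlapped a peak of the same factor in the other treatment is called a peak of both treatments. A peak without such a partner is called DMSO-only or dTAG-only, which states only that the other list held no overlapping call. Shares of peaks carry 95% Wilson intervals, and differences of shares carry intervals made from these by Newcombe's method. They cover counting error only and say nothing about the spread between samples. Chance overlap was the mean over 100 seeded random placements of each peak within its chromosome. Random placement takes no account of accessible or unmappable sequence. All 4 lists were merged into sites (overlap of at least 1 bp), and each site was recorded by the lists with a peak in it. Read numbers per library were not in the files, so the sequencing depth behind each list is unknown. The number of called peaks moves with depth as well as with binding.

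The plan fixed before the data were examined ranked peaks by the caller's q score, tested summit positions, and examined promoters, motifs and 13 gene lists (141 genes, among them the TAL1 complex, TAL1 targets, T cell receptor, thymocyte, NOTCH, B cell, myeloid and erythroid genes). The lists gave no q score or summit, and the gene table at hand was of GRCh38, another build than that of the peaks. Width within a list was therefore used in place of the q score, as deciles and quartiles, peak midpoints replaced summits, and promoters, motifs and gene lists were not analysed here. For the same reason regions are named by position and not by gene. The peaks named in the text are the 8 widest DMSO-only and the 8 widest dTAG-only peaks of each factor; other regions named were chosen after their values were seen and are marked so. Alternatives were an overlap of at least 50% of both peaks, midpoints within 100 bp, the widest 50% of each list, lists cut to equal length by width, peaks wider than 300 bp, windows of 50 kb in place of 100 kb, and all contigs.

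Overlap functions were tested on simulated lists with 3 planted shares per factor. In lists simulated from the 13879 DMSO GATA3 peaks the recovered share differed from the planted one by at most 0.15 percentage points, and in lists simulated from the 30649 DMSO RUNX1 peaks by at most 0.52. Computation used Python 3.11.15, pandas 2.3.3, numpy 2.4.6, scipy 1.17.1 and matplotlib 3.10.9.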

Results

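GATA3 and RUNX1 peaks were compared between DMSO-treated and dTAG-treated Jurkat cells that carry FKBP12-tagged TAL1. TAL1, a basic helix-loop-helix factor aberrantly expressed in T-ALL, is known to share many binding sites with GATA3, a zinc-finger factor of the T lineage, and RUNX1, a Runt-domain factor. The design sets out to compare where these partners sit on chromatin with and without the compound that targets TAL1. TAL1 protein or binding was not measured in the lists used here, so the extent of TAL1 loss is not known from them. With 1 library per antibody and treatment, every difference below compares 2 libraries and has no replicate check.

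The number of GATA3 peaks was nearly equal in both treatments, with 13879 in DMSO and 14005 in dTAG, a ratio of 1.01. RUNX1 had more peaks, 30649 in DMSO and 31759 in dTAG, a ratio of 1.04. RUNX1 peaks therefore outnumbered GATA3 peaks by 2.21 times in DMSO and by 2.27 times in dTAG. GATA3 peaks covered 4.57 Mb in DMSO and 4.93 Mb in dTAG, with median widths of 267 and 283 bp. RUNX1 peaks covered 13.9 Mb in DMSO and 14.0 Mb in dTAG, with median widths of 349 and 341 bp.

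The effect of dTAG on GATA3 occupancy was examined first. Of the DMSO GATA3 peaks, 61.9% (95% interval 61.1 to 62.7) overlapped a GATA3 peak in dTAG, and 60.9% (60.1 to 61.7) of the dTAG GATA3 peaks overlapped one in DMSO. Randomly placed peaks gave 0.324% and 0.323%. This left 5291 DMSO-only and 5474 dTAG-only GATA3 peaks, so that loss and gain of calls were close in number. The one-treatment peaks were narrow: DMSO-only peaks had a median width of 202 bp against 332 bp for DMSO peaks of both treatments, and dTAG-only peaks had 207 bp against 357 bp. The overlap rose with width, from 32.6% (30.2 to 35.1) in the narrowest decile of DMSO GATA3 peaks to 95.8% (94.6 to 96.8) in the widest. In the dTAG list it rose from 28.6% to 96.0%. A peak absent from one list can lie just under the calling threshold there. Within 1 kb of a GATA3 peak of the other treatment, without overlapping it, lay 631 DMSO-only and 774 dTAG-only GATA3 peaks.

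**Figure D1:**
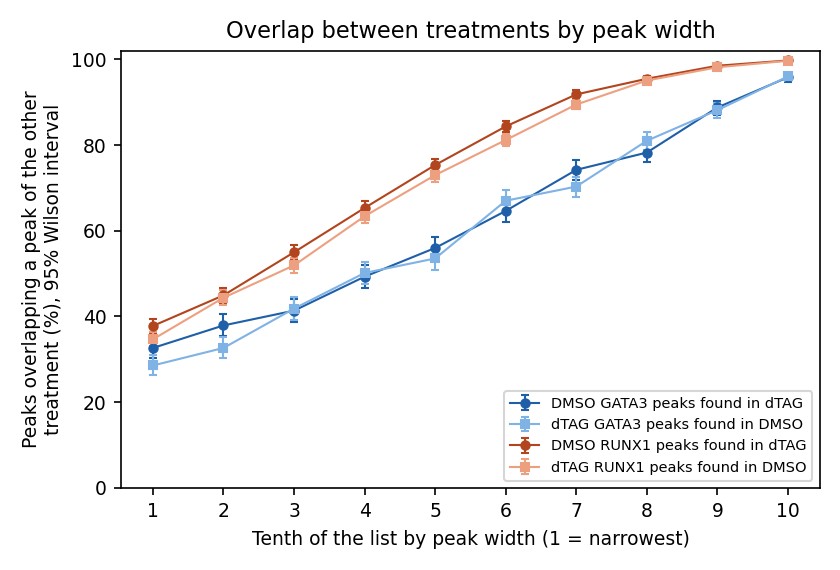
Share of peaks (percent, with 95% Wilson intervals) that overlap a peak of the same factor in the other treatment, by decile of peak width within each list, for GATA3 (blue) and RUNX1 (red). The widest decile reaches 95.8% for DMSO GATA3 and 99.7% for DMSO RUNX1, and the narrowest stays at 32.6% and 37.8%.

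The widest GATA3 peak found in DMSO only lay on chromosome 7 from 21466728 to 21468043 (1316 bp), and was 59th by width among all DMSO GATA3 peaks. It was followed by peaks on chromosome 5 from 118604299 to 118605278 (980 bp) and on chromosome 15 from 38988150 to 38989059 (910 bp). All 8 widest DMSO-only GATA3 peaks (785 to 1316 bp) overlapped RUNX1 peaks that were present in both treatments. The widest dTAG-only GATA3 peak lay on chromosome 3 from 34061819 to 34063270 (1452 bp, 62nd by width). The next lay on chromosome 1 from 3843643 to 3844842 (1200 bp) and on chromosome 9 from 70489398 to 70490454 (1057 bp). Of the 8 widest dTAG-only GATA3 peaks (862 to 1452 bp), 5 overlapped RUNX1 peaks in both treatments, and the first 2 overlapped none. Among the very widest peaks, regions on chromosome 18 from 107162 to 110027 and on chromosome 16 from 21846192 to 21848906 (named after their values were seen) were in both GATA3 lists. These regions were not checked for mapping artefacts.

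RUNX1 occupancy overlapped more between the treatments than GATA3 occupancy did. Of the DMSO RUNX1 peaks, 74.8% (74.3 to 75.3) overlapped a dTAG RUNX1 peak, and 73.1% (72.6 to 73.6) of the dTAG peaks overlapped a DMSO peak, against 1.10% and 1.06% for random placement. DMSO-only RUNX1 peaks numbered 7718 and dTAG-only RUNX1 peaks 8550. The overlap rose from 37.8% (36.1 to 39.5) in the narrowest decile of DMSO peaks to 99.7% (99.5 to 99.9) in the widest, where 8 of 3064 peaks had no partner. In the widest quartile, 1.47% of DMSO RUNX1 peaks lacked a partner (1.23 to 1.77), compared with 10.3% (9.35 to 11.4) of DMSO GATA3 peaks. The lists differ in length and depth is unknown, so the higher overlap of RUNX1 cannot be read as a difference in stability between the factors.

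The widest DMSO-only RUNX1 peaks lay on chromosome 20 from 62369211 to 62370483 (1273 bp, 885th by width in its list) and on chromosome 2 from 235345843 to 235347101 (1259 bp). The widest dTAG-only RUNX1 peaks lay on chromosome 1 from 156720105 to 156721163 (1059 bp, 1674th by width) and on chromosome 3 from 52016683 to 52017662 (980 bp). None of these 4 peaks overlapped a GATA3 peak. A GATA3 peak in either treatment was present at 1 of the 8 widest DMSO-only and at 2 of the 8 widest dTAG-only RUNX1 peaks. The widest RUNX1 peak of both lists (named after its values were seen) was on chromosome 16, from 85645524 to 85650821 in DMSO and from 85645529 to 85650528 in dTAG, and overlapped GATA3 in both treatments.

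Co-occupancy of the 2 factors was then compared between treatments. In DMSO, 61.1% (60.3 to 62.0) of GATA3 peaks overlapped a RUNX1 peak, and in dTAG 57.5% (56.7 to 58.3) did, with 0.833% and 0.864% for random placement. Of RUNX1 peaks, 27.2% (26.7 to 27.7) overlapped GATA3 in DMSO and 25.0% (24.5 to 25.5) in dTAG. With either RUNX1 list the dTAG GATA3 peaks had the lower share. DMSO GATA3 peaks overlapped the dTAG RUNX1 list at 60.9% (60.0 to 61.7), whereas dTAG GATA3 peaks overlapped the DMSO RUNX1 list at 52.2% (51.3 to 53.0). The share of dTAG GATA3 peaks thus also depended on the RUNX1 list, with 57.5% for the dTAG list and 52.2% for the DMSO list. The 2 lists of a treatment may share an IgG control. With an overlap of at least 50% of both peaks the shares of GATA3 peaks with RUNX1 were 29.0% (28.2 to 29.7) and 28.7% (28.0 to 29.5), and the treatments no longer differed beyond counting error. The dTAG share stayed lower with intervals apart in the other settings. Midpoints within 100 bp gave 35.6% (34.8 to 36.4) and 33.5% (32.7 to 34.3). The widest 50% of each list gave 51.4% (50.3 to 52.6) and 48.7% (47.6 to 49.9). Lists of equal length gave 40.2% (39.4 to 41.1) and 37.2% (36.4 to 38.0).

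Among 45865 merged sites, 4976 (10.8%) held a peak in all 4 lists and 13257 (28.9%) held RUNX1 in both treatments and GATA3 in neither. GATA3 in both treatments without RUNX1 was found at 2439 sites (5.32%). Sites with RUNX1 in both treatments lacked GATA3 only in dTAG in 2486 cases and lacked it only in DMSO in 1692 cases. Sites without RUNX1 in either treatment went the other way, with GATA3 in DMSO only at 1984 and in dTAG only at 2915.

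**Figure D2:**
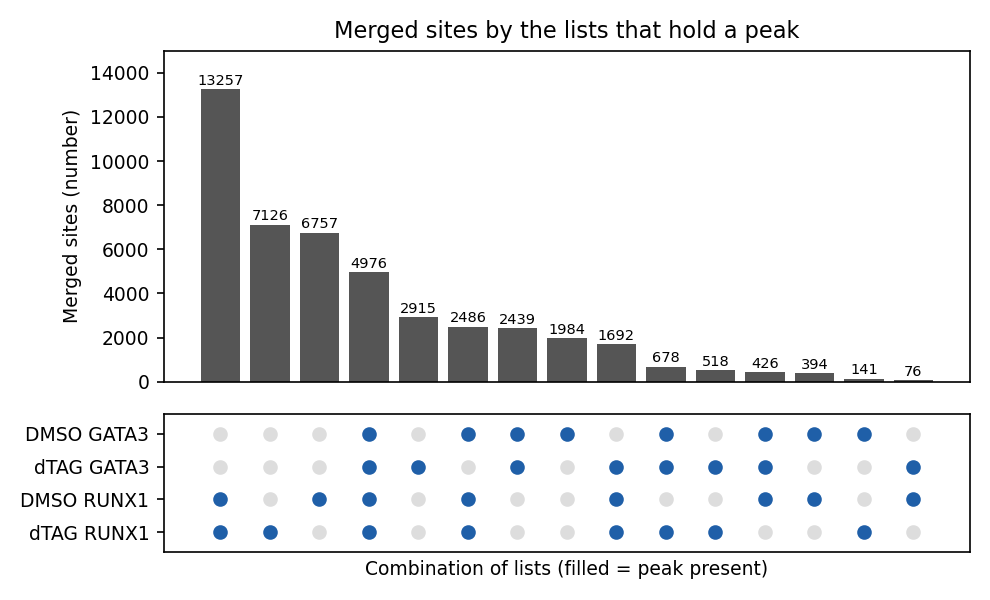
Number of merged sites (bars) for each combination of the 4 peak lists (filled circles mark the lists with a peak at the site). The largest class is RUNX1 in both treatments without GATA3 (13257 sites), and 4976 sites hold all 4.

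GATA3 peaks that were called in DMSO only lay at RUNX1 sites more often than those called in dTAG only. A RUNX1 peak of either treatment overlapped 62.5% (61.2 to 63.8) of DMSO-only GATA3 peaks and 46.7% (45.4 to 48.1) of dTAG-only ones, a difference of 15.8 percentage points (13.9 to 17.6). For GATA3 peaks of both treatments the share was 70.5% (69.5 to 71.5) in DMSO and 70.8% (69.9 to 71.8) in dTAG. These peaks were wider, so width quartiles were also compared. DMSO-only peaks had a lower share than DMSO peaks of both treatments in the narrowest quartile (52.2% against 56.3%). In the third quartile theirs was higher (74.9% against 68.5%), and in the others the intervals overlapped. The dTAG-only share was the lower in every quartile (53.3% against 66.1% in the third). Between DMSO-only and dTAG-only peaks the difference was 13.1 points in the narrowest quartile, 15.2 and 21.6 in the next 2, and 14.6 (8.53 to 20.5) in the widest. In the widest, 86.0% of DMSO-only and 71.5% of dTAG-only peaks overlapped RUNX1. At RUNX1 sites of both treatments, DMSO-only GATA3 peaks (2674) outnumbered dTAG-only ones (1867) by 1.43 times, and this direction held on 23 of 24 chromosomes. At sites without RUNX1 the numbers were 1984 and 2915, and dTAG-only peaks were more numerous on 23 of 24 chromosomes. The difference of 15.8 points was 12.6 (10.8 to 14.4) when the same peaks were matched to RUNX1 by midpoints within 100 bp, and 6.79 (5.15 to 8.42) when 50% of both peaks had to overlap. With the stricter rules also used between treatments, which enlarges the one-treatment sets to 7360 and 7486 or to 7237 and 7363 peaks, it was 10.5 (8.90 to 12.0) and 5.37 (3.93 to 6.81). Chromosomes of 1 library are not replicates, so the counts of chromosomes only describe how widely the order was spread.

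**Figure D3:**
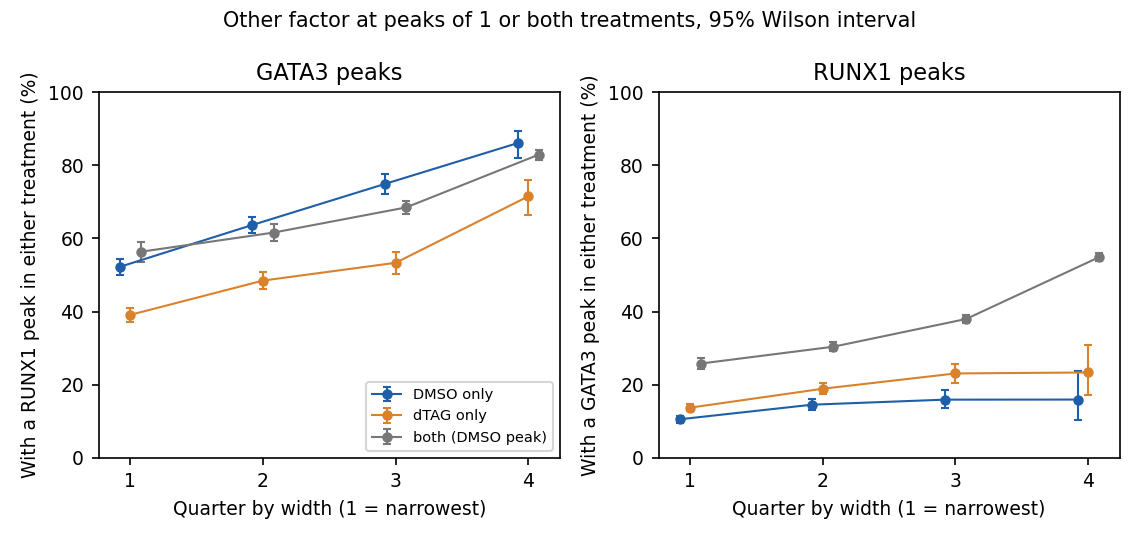
Share of peaks (percent, with 95% Wilson intervals) that overlap a peak of the other factor in either treatment, by width quartile within the list, for DMSO-only, dTAG-only and shared peaks of GATA3 (left) and RUNX1 (right). DMSO-only GATA3 peaks lie above dTAG-only ones in all 4 quartiles, by 13.1 to 21.6 points.

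GATA3 was also counted from the RUNX1 side. Of the 22931 DMSO RUNX1 peaks with a dTAG partner, 32.5% (31.9 to 33.1) overlapped GATA3 in DMSO and 29.0% (28.4 to 29.6) in dTAG. In the narrowest decile of these RUNX1 peaks the GATA3 share was 18.3% (16.7 to 19.9) in DMSO and 20.4% (18.8 to 22.1) in dTAG, and in the widest it was 54.9% (52.9 to 56.9) and 48.4% (46.4 to 50.5). RUNX1 peaks of 1 treatment showed the opposite order, with a difference over all widths that was smaller in percentage points but came from much lower shares. GATA3 overlapped 12.5% (11.7 to 13.2) of DMSO-only and 16.7% (15.9 to 17.5) of dTAG-only RUNX1 peaks, against 40.0% (39.4 to 40.7) of DMSO RUNX1 peaks with a partner. The difference, DMSO-only minus dTAG-only, was -4.20 points (-5.28 to -3.12) over all widths and -3.18, -4.36 and -7.16 points in the 3 narrower quartiles, with intervals below 0. In the widest quartile it was -7.40 points with an interval that includes 0 (-16.7 to 2.51), from 113 DMSO-only and 150 dTAG-only peaks. At GATA3 sites of both treatments, DMSO-only RUNX1 peaks numbered 445 and dTAG-only ones 707.

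**Figure D4:**
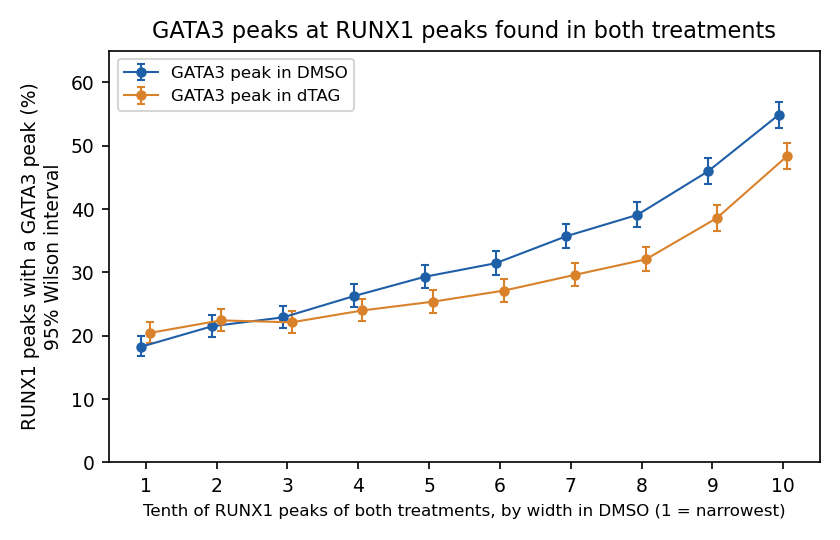
Share of RUNX1 peaks of both treatments (percent, with 95% Wilson intervals) that overlap a GATA3 peak in DMSO (blue) or dTAG (orange), by decile of DMSO RUNX1 width. The GATA3 share rises with RUNX1 width, from 18.3% to 54.9% in DMSO and from 20.4% to 48.4% in dTAG.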

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

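The RUNX1 overlap of GATA3 peaks with and without a partner in the other treatment was planned. The contrast of DMSO-only with dTAG-only peaks was not named in the plan. The tests by RUNX1 width decile, of same-treatment pairs and of the shortest peak were chosen after the values were seen. Each difference between the antibodies is between single libraries and was not tested against replicates.

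The share of one-treatment peaks that overlap the other factor moved in opposite directions for the 2 antibodies: it fell by 15.8 percentage points from DMSO-only to dTAG-only GATA3 peaks and rose by 4.20 points for RUNX1. DMSO-only peaks made up 58.9% (57.4 to 60.3) of one-treatment GATA3 peaks at RUNX1 sites of both treatments and 40.5% (39.1 to 41.9) at sites without RUNX1, which restates the same peaks and tests no explanation. A stronger general background at accessible, RUNX1-rich sites in the DMSO GATA3 library may account for the DMSO-only excess at RUNX1 sites. It needs a higher DMSO-only share at the widest RUNX1 peaks. Here the share was counted over RUNX1 peaks of both treatments that overlapped GATA3 in 1 treatment only, by decile of their DMSO width. It was 62.1% (58.2 to 65.8) in the widest decile and 40.1% (34.2 to 46.2) in the narrowest. The share rose with width up to decile 5, where it was 60.8% (56.0 to 65.4). From there to the widest decile the intervals overlapped, with 65.3% (61.2 to 69.1) in decile 9. Deciles by dTAG width were not counted. One-treatment calls of the 2 factors mostly fell in the same treatment (below). Ranking by DMSO width alone could therefore lower the DMSO-only share at narrow peaks without any background. For that reason the comparison cannot decide on background. It also does not address the dTAG-only excess at sites without RUNX1, nor the RUNX1 peaks. The design names treatment with the compound that targets TAL1, and no direction of change in GATA3. A loss of GATA3 from sites shared with RUNX1 upon degradation of TAL1 would also give a higher DMSO-only share at RUNX1 sites. It stays open as untested. Replicate libraries, read counts at fixed sites and TAL1 binding data would be needed to separate this loss from background.

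Where both factors had a call in 1 treatment only, it was mostly the same treatment. Such sites were a small part of the sites with GATA3 in 1 treatment. Both factors were called only in DMSO at 394 sites and only in dTAG at 518. GATA3 in DMSO only lay at 2486 sites with RUNX1 in both treatments and at 1984 without RUNX1. For GATA3 in dTAG only these numbers were 1692 and 2915. Among merged sites with a GATA3 peak in 1 treatment and a RUNX1 peak in 1 treatment, 912 paired the same treatment and 217 paired opposite treatments. The same-treatment share was 80.8% (78.4 to 83.0), where chance coincidence would give 50%, so chance is argued against. Same-treatment sites were 4.20 times as many as opposite-treatment sites. Cells, preparation or an IgG control shared by the libraries of a treatment predict an excess in this direction, just as a response to dTAG does. Neither predicts its size, and these cannot be told apart because there was 1 set of libraries per treatment.

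Peak width also moved in opposite directions. From DMSO to dTAG the median width rose by 16 bp for GATA3 and fell by 8 bp for RUNX1, and the shortest peak rose by 8 bp and fell by 4 bp. A difference in fragment length between the libraries is a candidate explanation, since MACS2 by default reports no peak shorter than the fragment length it estimates. The shortest peak changed by 1.06 times for GATA3 and 0.969 times for RUNX1, and the median width by 1.06 and 0.977 times, in the same directions. Over one-to-one pairs of overlapping peaks the median width ratio was 1.05 for GATA3 (8259 pairs) and 0.996 for RUNX1 (21211 pairs). A change in occupancy that widens GATA3 peaks stays open and was not tested.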

How the results depend on the processing

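No paired analysis was possible because each group had 1 sample, and no sample could be left out. Not run were the stricter q-value, lists cut by q score and summit distances (the lists hold neither), and the alternatives on promoters, motifs and gene lists (no hg19 annotation was at hand). Of the settings that follow, the 50% overlap on the shares, all contigs and every line of the files were planned before the data were examined, and the others were chosen after seeing the data. Of 64 recomputed values, 22 stayed within the interval of the reported value (or within 1.5 times a count) and 42 moved. Most are shares or counts that have no sign. With all contigs or every line of the files no value moved, but neither setting could change much. All contigs added at most 3 mitochondrial peaks per list. Counting every line repeated the main count, as no interval was listed more than once. These settings make up most of the values that stayed, while the planned 50% overlap moved every share.
With an overlap of at least 50% of both peaks, the share of DMSO GATA3 peaks with a dTAG partner was 47.9% and of dTAG peaks with a DMSO partner 47.4%, and for RUNX1 the shares were 58.7% and 56.6%. The share of GATA3 peaks with RUNX1 was 29.0% in DMSO and 28.7% in dTAG, and of RUNX1 peaks with GATA3 13.1% and 12.7%, so that the lower co-occupancy in dTAG was within counting error under this setting. With midpoints within 100 bp the same 8 shares were 47.0%, 46.5%, 53.0%, 51.2%, 35.6%, 33.5%, 16.1% and 14.8%. In the widest 50% of each list they were 63.4%, 62.4%, 78.0%, 76.0%, 51.4%, 48.7%, 23.1% and 21.4%. In lists cut to equal length by width, the share of DMSO RUNX1 peaks with a dTAG partner was 73.8% and that of dTAG peaks with a DMSO partner 74.5%, so that their order turned, GATA3 peaks overlapped RUNX1 at 40.2% in DMSO and 37.2% in dTAG, and RUNX1 peaks overlapped GATA3 at 38.6% and 35.9%.
The difference of 15.8 points in RUNX1 overlap between DMSO-only and dTAG-only GATA3 peaks was 12.6 points with midpoints and 6.79 with the 50% overlap when only the match to RUNX1 was changed, and 10.5 and 5.37 when the match between treatments was changed too. It kept its sign in every setting run and stayed between 14.4 and 16.4 points with RUNX1 in both lists, RUNX1 of the same treatment, the widest 50% of all lists, or peaks within 1 kb of a partner left out. Peaks wider than 300 bp numbered 5863 and 6469 for GATA3 and 17643 and 17921 for RUNX1 in DMSO and dTAG; where settings moved values, the cause was not tested beyond the stricter definition itself. Unknown depth limits every count of peaks and every one-treatment call.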

Other observations

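The windows and the test in this part were chosen after the values were seen. Peaks were also counted in windows of 100 kb. The window with most RUNX1 peaks, on chromosome 1 from 228700001 to 228800000, held 44 RUNX1 peaks in DMSO and 43 in dTAG, and also 16 and 17 GATA3 peaks. A window on chromosome 10 from 63500001 to 63600000 held 16 GATA3 peaks in DMSO and 17 in dTAG. One on chromosome Y from 13400001 to 13500000 held 17 and 16, and one on chromosome 11 from 128500001 to 128600000 held 13 in each. Repeated sequence was not filtered out, so a dense window can hold mapping artefacts and need not reflect dense binding. The largest imbalances toward dTAG were on chromosome 3 from 107800001 to 107900000, with 4 GATA3 peaks in DMSO and 11 in dTAG, and on chromosome 1 from 158300001 to 158400000, with 5 and 13 RUNX1 peaks. The largest imbalances toward DMSO were on chromosome 17 from 79800001 to 79900000, with 22 RUNX1 peaks in DMSO and 11 in dTAG, and from 38400001 to 38500000, with 14 and 5. None of these stands out from shuffled treatment labels: the excess of one-treatment peaks was 7 in the GATA3 window and 8 and 10 in the RUNX1 windows with the largest imbalance toward dTAG and DMSO, and the central 95% of the largest excess in shuffles reached up to 7, 11 and 10.

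A hypothesis that GATA3 peaks were gained together over whole neighbourhoods in dTAG was tested by shuffling the treatment labels of one-treatment peaks 1000 times. Windows with at least 4 more dTAG-only than DMSO-only GATA3 peaks numbered 29, and the central 95% of shuffles ran from 14.0 to 31, which holds the observed number. For DMSO-only GATA3 peaks the number was 17 (11 to 28 in shuffles), and for RUNX1 it was 59 toward DMSO (40 to 65) and 71 toward dTAG (64.0 to 97). In windows of 50 kb, also chosen after the values were seen, every count was lower by more than 1.5 times. GATA3 windows toward dTAG then numbered 17, just above the 5 to 16 of shuffles, while the count at 100 kb lay just inside its range. Both lie near the limit, and several counts were compared without correction for their number. The shuffles therefore cannot decide, and a regional gain of GATA3 is left open. The other counts lay within the shuffles, with 7 GATA3 windows toward DMSO (4 to 15.0), 31 RUNX1 windows toward DMSO (18 to 37) and 44 toward dTAG (30 to 53).

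Peaks on the mitochondrial genome, left out of all comparisons, numbered 3 for GATA3 in DMSO and 0 in dTAG, and 1 and 2 for RUNX1.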
